A study of Saccharomyces cerevisiae with 112 samples.

How the data were processed

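Of the 112 samples, those without files were not analysed here, and the analysis used the deposited tables of the other 40. Together they list 5560 yeast features, most of them windows at the 3' ends of genes, with the chromosome, start, end and strand of each. A feature missing from a library was counted as 0. The 9 spike-in features, of which 6 had reads, were taken from the chase libraries only. RNA was alkylated before SLAM-seq and libraries were made with a 3' end kit, per the labels' protocols, and the tables were written by slamdunk 0.4.3, per the file headers. Cutadapt, Bowtie, TopHat2 and featureCounts are named, without versions, per the submitters' processing notes, which do not say which samples each was used for. The aligner settings, the number of conversions that makes a read labelled, the genome build and the way the spike-in was added are not given in the sources used here. Of the feature names, 5558 matched a locus tag of a gene table of the organism, which gave the symbols, and 2 did not.

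The deposited read count per feature, the count of reads with T-to-C conversions (labelled reads), the covered T positions, the conversions on them and the multimapped reads are whole-number counts per the file headers. The deposited conversion rate is a fraction of conversions over covered T positions, per the file headers. The deposited CPM values are counts scaled to the library total, per the file headers, and entered no test. The totals of yeast reads ran from 2710630 to 10591665 in the chase libraries, 14966015 to 31072472 in the 4TU libraries of total RNA and polysomes, and 15482446 to 29223067 in those without 4TU, and multimapped reads made up 0.25% to 1.7% of reads. The variance between replicates was at least 4.02 times the counting variance, and up to 134.6 times.

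Samples were grouped by their titles into 14 chase groups (with or without glucose at 7 times), 4 groups with 4TU (total RNA or polysomes, with glucose or after withdrawal) with 2 libraries each, and 4 groups without 4TU with 1 library each, 22 groups in all. The groups, tests, samples in each fit, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. Abundance in total RNA, abundance in the chase at 30 min and at the other times, and the change of polysome association were tested on the read counts with edgeR 4.0.16 in R 4.3.3, using TMM factors, its expression filter, the robust quasi-likelihood test and Benjamini-Hochberg adjustment with a threshold of 0.05. The 8 libraries with 4TU entered one fit and the 28 chase libraries another. Values are relative to other mRNAs in the library, so a change of all mRNA at once is not seen.

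Labelling was tested in edgeR with a labelled and an unlabelled column per library, an intercept per library and the same library size for both columns, so that the tested term is the log2 odds of labelled against unlabelled reads. Genes needed a mean of at least 50 reads per library and at least 10 labelled reads in sum. The contrasts were polysomes against total RNA without glucose, the same with glucose, the difference of these contrasts, and total RNA without against with glucose. In the chase the labelled odds had an intercept and a slope over 0 to 45 min for each condition, and the slopes were compared and are given per 10 min. This fit takes the 28 libraries as independent, although the times of a course may be repeated samples of 1 culture. Limma on 1 slope per course does not, but its slopes are those of the log2 labelled share and not of the odds. The slope of the share cannot tell the loss of labelled copies from the making of unlabelled or labelled ones. Library-wide shares of labelled reads were compared with an exact two-sided permutation test in SciPy 1.17.1, in 11 comparisons, and shares of single libraries have 95% Wilson or exact intervals.

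The 16 gene lists with measured members were heat shock chaperones, general stress, glucose-repressed carbon metabolism, hexose transport and phosphorylation, glycogen and trehalose, glycolysis and fermentation, cytosolic ribosomal proteins, ribosome biogenesis, translation factors, mRNA decay and P-body, nuclear genes of the respiratory chain and ATP synthase, TCA cycle, amino acid biosynthesis, cell cycle regulators, histones, and ergosterol and cell wall. They were written from general knowledge of yeast, and a list of 8 mitochondrially encoded genes had no member in the files. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison, and again with an estimated correlation. Camera compares a list with the other genes by test statistics, so its direction can differ from the sign of the list's median. The 1298 genes higher at 30 min of the chase with a log2 change of at least 1 and the 1002 genes lower by as much formed lists tested in the polysome comparisons. For lists in the unreplicated libraries, the median was placed among 10000 random lists matched on expression.

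Named genes were, for each comparison, the 5 with the largest change in each direction among genes past the threshold, with the same direction in both replicates and a mean of at least 100 reads, leaving out features with over 20% multimapped reads, and the 2 members of each list with the smallest p-value. Such genes were also followed into other comparisons. RPL14B, SUB1, REC107, GAL3 and FKH2 were named as all the genes lower in the difference of labelled odds, and genes were otherwise named outside the rule only where few were called. Genes with near-identical copies, such as HXT6 and HXT7 and many ribosomal protein pairs, are uncertain where reads can be split between copies.

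The alternatives fixed then were DESeq2 1.42.0, its size factors in edgeR, library totals, no filter, a fit of the compared libraries alone, genes without multimapped reads, other read minimums of 10 and 200, conversions per covered T, subtraction of the background without 4TU, a reference set to the transcriptome-wide labelled share, labelled reads over library totals, shorter chase windows, limma on 1 slope per course, the replicate number as a block and the omission of each library. Scaling to the spike-in, labelled reads per spike-in read, a fit of the libraries without glucose alone, omission of 262 genes with over 5% labelled reads after withdrawal, subtraction of labelled reads expected from the glucose libraries, factors without ribosomal protein genes and the test of the chase against the total RNA were added after seeing the data. Each test was tested on simulated data drawn for the real genes with 200 changed genes. At a log2 change of 1 it recovered 71% of changed genes for total RNA, 94% for the chase at 30 min, 23% for polysome association, 52% for the chase against total RNA, 12.1% for the labelled share without glucose, 85% with glucose, 5% for their difference and 90% for total RNA. At a log2 change of 2 it recovered 100%, 100%, 96%, 99%, 42%, 98%, 35% and 96% in that order, and for the chase slope 78% at 0.25 and 98% at 0.5 per 10 min. No changed gene passed the threshold with the wrong sign. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.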

Results

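SLAM-seq marks RNA that was made while cells took up 4-thiouracil (4TU), since the incorporated base is later read as a T-to-C conversion. Libraries of this kind from budding yeast address how quickly mRNAs are lost with and without glucose, and whether mRNA made around a sudden removal of glucose is enriched on polysomes. Processed files were available for 40 of the 112 samples, and the other 72 were not analysed here. The chase set was made from strain KWY165 and held 28 libraries, from 2 courses with glucose and 2 without it, each sampled at 0, 5, 10, 15, 20, 30 and 45 min. The polysome set was made from strain KWY11376 and held 8 libraries, 2 each of total RNA and of polysomes, after 30 min of 4TU in glucose or at 30 min without glucose. The titles of the latter add the words post-labeling (4TU), which leave open whether 4TU was given before or after the withdrawal. Total RNA and polysomes of KWY165 without 4TU, with and without glucose, gave the background in 1 library each, without replicates. The chase libraries held 2710630 to 10591665 reads over 5560 yeast features, the 4TU polysome set 14966015 to 31072472, and the libraries without 4TU 15482446 to 29223067. No source says that replicates were separate cultures, so p-values measure only the spread between these samples, and intervals on single shares cover counting error only. Gene positions are those of the files, whose genome build is not given in the sources used here.

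Total RNA 30 min after withdrawal was first compared with total RNA in glucose, which asks which mRNAs changed their share of the pool. Genes for the use of carbon sources other than glucose rose together: 28 of 29 members rose and the other did not pass the test, with a median log2 change of 3.21. JEN1 (YKL217W), a lactate transporter, rose by 5.69 ± 0.228 (log2 ± SE, n = 2 per group) and POT1 (YIL160C), an enzyme of fatty acid oxidation, by 5.81 ± 0.249. General stress genes, of the kind under Msn2 and Msn4, rose in 30 of 32 members (31 adjusted over the list alone), with a median of 2.88. The list of heat shock chaperones, which also takes in heat shock genes that need not encode chaperones, rose in 17 of 27 members and fell in 1. It was led by the heat shock genes HSP30 (YCR021C, 7.44 ± 0.298) and HSP26 (YBR072W, 5.22 ± 0.243). Hexose transport and phosphorylation genes rose in 12 of 18 and fell in 1. HXT6 (YDR343C, chromosome IV, 1159070 to 1159858), a high-affinity glucose transporter, rose 142-fold. Its near-identical neighbour HXT7 makes that value uncertain. In the other direction, ribosome biogenesis genes fell in 60 of 62 members with none higher, at a median of -1.62, and RRS1 (YOR294W) fell by 2.74 on the log2 scale.

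The count adjusted over the list alone was the same as over all genes for these lists unless given. By camera, adjusted p was 4.25e-26 for the glucose-repressed list, 1.52e-25 for general stress, 4.58e-09 for chaperones and for hexose transport, and 3.18e-17 for ribosome biogenesis. With an estimated correlation the glucose-repressed call held at adjusted p = 0.0431. The other calls were lost, at adjusted p = 0.0533 with an estimated correlation for general stress and for hexose transport, 0.207 for chaperones and 0.161 for ribosome biogenesis. Glycogen and trehalose genes rose in 17 of 21 and fell in 1 (median 1.62; camera adjusted p = 9.59e-09, and adjusted p = 0.122 with an estimated correlation), with GLC3 (YEL011W), the branching enzyme, up by 4.55 ± 0.208. Nuclear genes of the respiratory chain and ATP synthase rose in 31 of 40 (32 adjusted over the list alone; median 0.84; camera adjusted p = 1.43e-05, and adjusted p = 0.242 with an estimated correlation). Glycolysis and fermentation genes rose in 5 of 22 and fell in 2 (median 0.42; camera adjusted p = 0.0375, and adjusted p = 0.522 with an estimated correlation). Among them the minor glyceraldehyde-phosphate dehydrogenase gene TDH1 (YJL052W) rose by 4.04 ± 0.242. Genes of the TCA cycle rose in 10 of 17 and fell in 3 (median 0.50), and the list did not pass (camera adjusted p = 0.0723).

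Lists that fell included translation factors, lower in 23 of 38 with none higher (median -0.55; camera adjusted p = 0.00117, and adjusted p = 0.241 with an estimated correlation). Amino acid biosynthesis genes fell in 25 of 57 and rose in 5 (4 adjusted over the list alone; median -0.40; camera adjusted p = 0.000241, and adjusted p = 0.219 with an estimated correlation), with the branched-chain enzyme gene ILV5 (YLR355C) at -3.64 ± 0.214. Cell cycle regulators fell in 21 of 32 and rose in 2 (22 and 3 adjusted over the list alone; median -1.35; camera adjusted p = 1.36e-05, and adjusted p = 0.0588 with an estimated correlation). The G1 cyclin gene PCL1 (YNL289W) stood at -4.08 ± 0.350. Genes of mRNA decay and P-bodies fell in 15 of 37 and rose in 3 (median -0.46; camera adjusted p = 0.0264, and adjusted p = 0.207 with an estimated correlation), and the helicase gene DHH1 (YDL160C) was one of those that rose, 4.91-fold. Cytosolic ribosomal protein genes rose in 39 of 137 and fell in 11 (35 and 10 adjusted over the list alone) at a median of 0.21, which turned to -0.21 with library totals, where 18 rose and 42 fell. The list did not pass (camera adjusted p = 0.344). RPS28B (YLR264W) stood at -2.26 ± 0.216 and RPL1B (YGL135W) at 2.07 ± 0.209, and reads of such gene pairs can be split between copies. Histone genes rose in 4 of 10 (median 0.38, and -0.06 with library totals; camera adjusted p = 0.270). Ergosterol and cell wall genes rose in 9 of 35 and fell in 5 (8 and 5 adjusted over the list alone). Their median of 0.03 turned to -0.38 with library totals, and the camera statistic pointed down (adjusted p = 0.959). Library totals also moved the medians to 0.42 for respiratory genes (18 higher and 2 lower of 40), 0.07 for TCA genes, 0.0032 for glycolysis and 0.73 for chaperones (4 lower). They moved them to -0.97 for translation factors, -0.83 for amino acid genes and -0.86 for mRNA decay genes (25 lower of 37). With them 1 cell cycle regulator was higher, 1 histone gene was higher and 1 lower, and 3 ergosterol and cell wall genes were higher and 15 lower. None of the 8 mitochondrially encoded genes was among the features.

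By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1628 of 5541 genes were higher and 1624 lower without glucose. The largest rises by the fixed rule also included ATG15 (YCR068W, 184-fold), a vacuolar lipase, YNL194C (149.6-fold) and BSC1 (YDL037C, 134-fold), and the largest falls HLR1 (YDR528W, 26.4-fold), CBP1 (YJL209W), TRF5 (YNL299W) and RAX2 (YLR084C). In the chase at 30 min the log2 changes were 1.71 for ATG15, 7.87 for YNL194C and 5.85 for BSC1. There they were -2.30 for HLR1, -0.72 for CBP1, -1.97 for TRF5 and -2.80 for RAX2, so some of these sizes, above all that of ATG15, were far smaller. With library totals in place of TMM factors the split was 1052 higher and 2344 lower and the median of all genes moved from -0.02 to -0.45, so directions are relative to the TMM reference. In the unreplicated libraries without 4TU, 1545 of the 1617 higher genes with enough reads were also higher and 1449 of 1617 lower genes also lower. There the medians were 2.49 for glucose-repressed genes, 2.70 for general stress and -1.22 for ribosome biogenesis, and ribosomal protein genes stood at -0.95.

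The chase libraries gave the same abundance comparison in another strain, here at 30 min. All 32 general stress genes rose, at a median log2 change of 4.01, with STF2 (YGR008C), a regulator of the mitochondrial ATP synthase, up by 5.65 ± 0.189 (SE, n = 2 per group). All 29 glucose-repressed genes rose (median 2.67), among them the regulator CAT8 (YMR280C, 6.12 ± 0.235). Glycogen and trehalose genes rose in 19 of 21 (median 3.05), with the glycogen phosphorylase gene GPH1 (YPR160W) 122.6-fold higher, and hexose genes rose in 15 of 18 and fell in 1 (median 2.98), with HXK1 (YFR053C), a hexokinase, 116-fold higher. Ribosomal protein genes fell in 136 of 137 (median -2.02), and the other did not pass the test. Part of this difference lay in the courses with glucose. At 30 min reads of the list per spike-in read came there to 1.74 and 1.08 times the 0 min value, and all genes to 1.33 and 0.806 times. Without glucose the list came to 0.249 and 0.327 times, and all genes to 0.561 and 0.687 times. That list differed between the experiments, as a direct test of the difference gave a median of -2.28, with 134 of 137 members lower in the chase and 2 higher (camera adjusted p = 4.35e-79, and adjusted p = 0.364 with an estimated correlation). All 62 ribosome biogenesis genes fell (median -2.09), among them the nucleolar methyltransferase gene NOP1 (YDL014W, -2.96 ± 0.158). Counts adjusted over the list alone were the same for every list of this comparison but the amino acid one.

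Camera passed these lists with adjusted p = 1.60e-26 for general stress, 5.43e-14 for glucose-repressed, 1.69e-18 for glycogen and trehalose, 5.19e-09 for hexose genes and 2.41e-44 for ribosomal proteins. With an estimated correlation these calls held, at adjusted p = 0.00173, 0.00136, 0.00173, 0.00242 and 0.0220 in that order, and ribosome biogenesis (5.78e-20) was lost at adjusted p = 0.102 with an estimated correlation. Translation factors fell in 33 of 38 and rose in 1 (median -1.30; camera adjusted p = 8.29e-10, and adjusted p = 0.0485 with an estimated correlation). Chaperones rose in 24 of 27 and fell in 1 (median 2.17; camera adjusted p = 1.06e-09, and adjusted p = 0.129 with an estimated correlation), with the disaggregase gene HSP78 (YDR258C) up by 4.64 ± 0.212. All 40 respiratory genes rose (median 1.46; camera adjusted p = 5.31e-12, and adjusted p = 0.0721 with an estimated correlation), led by CYC7 (YEL039C), a cytochrome c isoform, at 62.8-fold. TCA cycle genes rose in 11 of 17 and fell in 4 (median 1.31; camera adjusted p = 0.0131, and adjusted p = 0.249 with an estimated correlation). Amino acid biosynthesis genes fell in 34 of 57 and rose in 7 (35 and 7 adjusted over the list alone; median -0.60; camera adjusted p = 0.000244, and adjusted p = 0.148 with an estimated correlation). Cell cycle regulators fell in 20 of 32 and rose in 3 (median -1.08; camera adjusted p = 0.00149, and adjusted p = 0.102 with an estimated correlation), the B-type cyclin gene CLB6 (YGR109C) standing at -3.48 ± 0.274.

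The remaining lists of the chase at 30 min did not pass camera. Glycolysis genes rose in 7 of 22 and fell in 4 (median 0.17, and -0.31 with spike-in scaling; adjusted p = 0.164), although the enolase gene ENO1 (YGR254W) rose 18.2-fold. Genes of mRNA decay rose in 7 of 37 and fell in 14 (median -0.25, and 0.05 with library totals; adjusted p = 0.353). Histone genes rose in 5 of 10 and fell in 2 (median 0.26, and -0.23 with spike-in scaling; adjusted p = 0.789). Ergosterol and cell wall genes rose in 11 of 35 and fell in 14, with a median of -0.11, or 0.19 with library totals, and a mean of 0.05 (adjusted p = 0.643). With spike-in scaling the medians were -1.08 for amino acid genes (1 higher), -0.72 for mRNA decay genes (3 higher), 0.84 for TCA genes and -0.58 for ergosterol and cell wall genes (5 higher), and 10 glycolysis genes were lower and 0 histone genes higher by edgeR. With library totals they were 0.46 for glycolysis (11 higher and 2 lower), -0.31 for amino acid genes and 0.56 for histones, and 8 cell cycle regulators and 11 mRNA decay genes were higher. By edgeR, 2117 of 5525 genes were higher and 1918 lower, and the largest changes were YNL194C (7.87 ± 0.269), RGI1 (YER067W, 7.84 ± 0.234), HXT6, TMA10 (YLR327C) and POT1 upwards, and RPS28B (-4.22 ± 0.168), RPA12 (YJR063W), CLB6, ALB1 (YJL122W) and SNU13 (YEL026W) downwards. With library totals the split was 2622 higher and 1409 lower (median of all genes 0.36 against 0.06), and with scaling to the spike-in reads it was 1186 higher and 2446 lower (median -0.42).

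**Figure D1:**
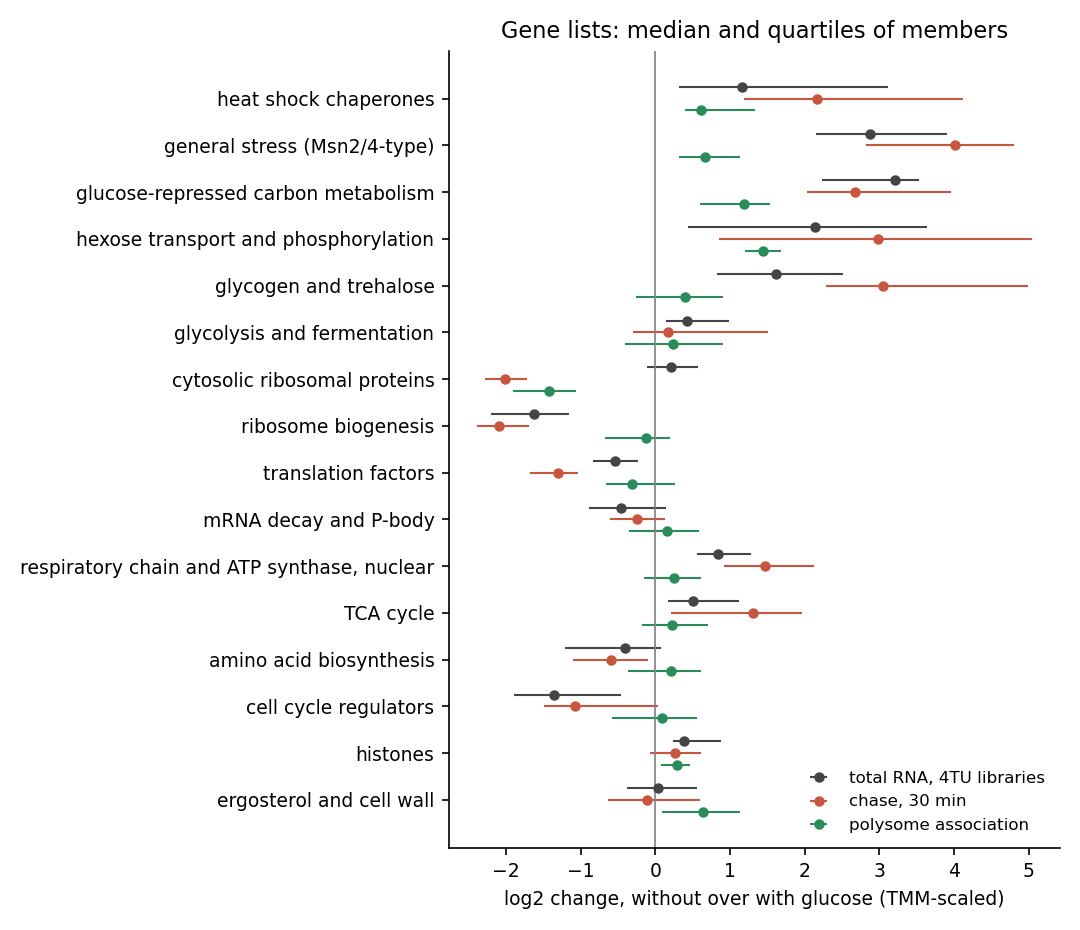
Median (points) and quartiles (bars) of the log2 change without over with glucose (x axis, TMM-scaled) over the members of each of 16 fixed gene lists (y axis), for total RNA of the 4TU libraries, the chase at 30 min and polysome association. General stress genes lay at 2.88 and 4.01 in the first comparisons, while ribosomal protein genes lay at 0.21 in total RNA (-0.21 with library totals), -2.02 in the chase and -1.43 in polysome association.

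At 5 min of the chase, 18 of 40 respiratory genes, 12 of 27 chaperones, 9 of 21 glycogen and trehalose genes, 7 of 18 hexose genes and 11 of 32 general stress genes had risen. The respiratory median was already 0.26 at 0 min and 0.35 at 5 min, so most of that difference was there at the start. From 0 to 5 min the medians went from -0.28 to 0.40 for chaperones, 0.10 to 0.58 for glycogen, -0.21 to 0.27 for hexose and 0.10 to 0.52 for general stress genes. General stress genes had risen in 27 at 10 min (median 1.59), 30 at 15 min (2.71) and 31 at 45 min (4.56), and glycogen genes in 18 at 10 min (1.83). Glucose-repressed genes had risen in 2 of 29 at 5 min, 26 at 15 min (median 1.52) and 29 at 45 min (3.55). Ribosome biogenesis genes fell in 13 of 62 at 5 min, 51 at 10 min and all 62 at 15 min (median -1.18), reaching -2.55 at 45 min. Ribosomal protein genes fell in 47 of 137 at 5 min (median -0.35), 122 at 15 min (-0.89) and 136 at 45 min (-2.75). Across all genes, edgeR called 6 higher and 22 lower at 0 min, 450 and 301 at 5 min, 1232 and 1008 at 10 min, 1706 and 1439 at 15 min, 1885 and 1637 at 20 min, and 2210 and 2036 at 45 min. The order of the lists was not itself tested. The chase at 30 min and the total RNA of the polysome set share no library. Of 5522 genes tested in both, 1229 were higher in both, where independent lists would share 623, and 1090 were lower in both, where they would share 564. Another 289 genes were called in opposite directions, and across genes, which are not independent replicates, log2 changes correlated with Pearson r = 0.70 and Spearman rho = 0.652.

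Polysome association was measured as reads in polysomes over total RNA, and its change with withdrawal asks which mRNAs gained or lost polysome share relative to other mRNAs. Hexose transport and phosphorylation genes gained in 12 of 18 with none lost (15 gained and 1 lost adjusted over the list alone), at a median log2 change of 1.44. The transporter genes HXT3 (YDR345C) and HXT2 (YMR011W) gained 2.00 ± 0.259 and 2.13 ± 0.325 (SE, n = 2 per group). Glucose-repressed genes gained in 17 of 29 (18 adjusted over the list alone; median 1.18), including the acetyl-CoA synthetase gene ACS1 (YAL054C, 2.39 ± 0.340) and JEN1 (1.68 ± 0.270). Chaperones gained in 12 of 27 and lost in 1 (13 and 1 adjusted over the list alone; median 0.61), with HSP26 at 1.81 ± 0.290, and general stress genes gained in 14 of 32 (16 adjusted over the list alone; median 0.66). Ribosomal protein genes lost in 110 of 137 and gained in 1 (124 and 2 adjusted over the list alone; median -1.43), among them RPS19B (YNL302C, -3.00 ± 0.323) and RPS3 (YNL178W, -2.84 ± 0.319). DHH1 gained 2.05 ± 0.264.

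Camera passed hexose genes (adjusted p = 6.70e-11), glucose-repressed genes (6.50e-12) and ribosomal proteins (6.11e-66), and each was lost at adjusted p = 0.0876 with an estimated correlation. Chaperones (8.56e-08) and general stress (1.62e-06) were lost at adjusted p = 0.352 with an estimated correlation. Ergosterol and cell wall genes gained in 13 of 35 and lost in 2 (16 and 2 adjusted over the list alone; median 0.64; camera adjusted p = 0.000205, and adjusted p = 0.562 with an estimated correlation), and the wall protein gene PIR3 (YKL163W) gained 1.94 ± 0.354. Glycogen and trehalose genes gained in 3 of 21 (5 adjusted over the list alone; median 0.39; camera adjusted p = 0.0342, and adjusted p = 0.598 with an estimated correlation). With library totals 6 general stress genes (median 0.41) and 10 glucose-repressed genes gained, and the medians of chaperones, ergosterol and cell wall genes and glycogen genes were 0.39, 0.41 and 0.15. The other lists did not pass. Ribosome biogenesis genes lost in 7 of 62 (median -0.12; adjusted p = 0.0564) and translation factors lost in 8 of 38 and gained in 3 (9 and 3 adjusted over the list alone; median -0.32; adjusted p = 0.0564). Respiratory genes gained in 6 of 40 and lost in 5 (median 0.25; adjusted p = 0.128), TCA cycle genes gained in 3 of 17 (median 0.22; adjusted p = 0.187), and no histone gene of 10 was called by edgeR (median 0.29; adjusted p = 0.378). Library totals put these 5 medians at -0.33, -0.54, 0.02, 0.02 and 0.05 in that order, with 1 TCA gene gained. Under library totals the medians of 4 further lists turned from 0.23 to -0.01 for glycolysis (4 gained and 3 lost of 22, 5 and 3 adjusted over the list alone; adjusted p = 0.429), from 0.15 to -0.11 for mRNA decay (5 and 3 of 37; adjusted p = 0.467), from 0.21 to -0.01 for amino acid biosynthesis (4 and 3 of 57, 4 and 2 adjusted over the list alone; adjusted p = 0.330) and from 0.08 to -0.17 for cell cycle regulators (2 and 2 of 32; adjusted p = 0.997).

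By edgeR, 449 of 5541 genes gained polysome association and 442 lost it. The largest gains by the rule were YOR343C (3.02 ± 0.560), SWP1 (YMR149W), APE1 (YKL103C), a vacuolar aminopeptidase, AQY1 (YPR192W) and FLR1 (YBR008C), and the largest losses PSF3 (YOL146W, -4.11 ± 0.784), RPA43 (YOR340C), RPS19B, COG3 (YER157W) and RPS3. The 1298 genes higher at 30 min of the chase, a list from other libraries, had a median of 0.37, with 235 gained and 33 lost (258 and 36 adjusted over the list alone; camera p = 1.29e-10, and p = 0.0755 with an estimated correlation). The 1001 tested genes of the matching lower list had a median of -0.36, with 33 gained and 204 lost (45 and 227 adjusted over the list alone; camera p = 8.67e-11, and p = 0.0870 with an estimated correlation). With library totals 224 gained and 516 lost (median of all genes -0.22 against 0.01). Without replicate 1 of total RNA without glucose 178 gained and 174 lost, and without its replicate 2 212 gained and 205 lost. In the unreplicated libraries without 4TU, 351 of 445 gains and 389 of 442 losses had the same sign.

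Labelled reads made up 50.1% ± 1.03 (SD, n = 2) of total RNA after 30 min of 4TU in glucose and 28.5% ± 3.70 of polysomes. After withdrawal they made up 1.72% ± 0.0974 of total RNA and 1.58% ± 0.00162 of polysomes. The libraries without 4TU gave a background of 0.0397% (95% Wilson interval 0.0389 to 0.0406) for total RNA in glucose, 0.0502% (0.0491 to 0.0513) for total RNA without glucose, 0.0369% for polysomes in glucose and 0.0351% for polysomes without it. HXT7 (YDR342C), a glucose transporter whose reads cannot be told from those of HXT6 with certainty, was labelled in 67.7% ± 3.22 of reads in glucose and in 1.39% ± 0.224 after withdrawal. Genes at least 8-fold higher at 30 min of the chase had a median labelled share of 1.62% and 1.48% in the total RNA libraries without glucose, and genes that changed by less than 0.5 (log2) had 1.38% and 1.28%. Both sets leave out genes over 5% labelled after withdrawal and genes with under 200 reads, which by itself keeps these medians low. Polysomes over total RNA came to a ratio of 0.568 in glucose, which was 0.428 from conversions per covered T and 0.700 for the median gene, and to 0.914 without glucose. Labelled reads held 0.335 to 0.614 conversions each in the 4TU libraries and 1.32 to 1.75 in the chase libraries, so labelled reads and conversions of the 4TU libraries were not counted alike. At 0 min of the chase 61.1% ± 0.0865 of reads were labelled with glucose and 62.5% ± 0.217 without, at 30 min 30.8% ± 0.732 and 47.1% ± 1.36, and at 45 min 18.6% ± 0.337 and 36.9% ± 2.76. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, which all 11 comparisons gave, also after Benjamini-Hochberg adjustment.

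**Figure D2:**
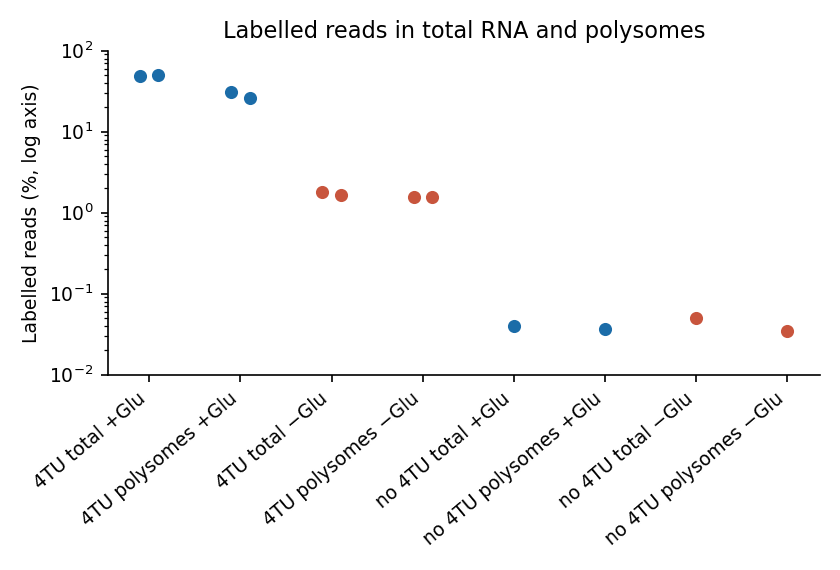
Labelled reads as a percentage of yeast reads (y axis, log axis) for each 4TU and no-4TU library (points) by group (x axis). Total RNA in glucose lay at 50.1% on average, total RNA after withdrawal at 1.72% and the 4 libraries without 4TU at 0.0351% to 0.0502%.

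Whether labelled copies of a gene were enriched on polysomes was tested as the log2 odds of labelled against unlabelled reads in polysomes over total RNA. In glucose, labelled copies were depleted, with a median over all genes of -1.02, near which the medians of several lists below lie. Of the glycolysis genes 19 of 21 were lower (median -1.46), and the enolase gene ENO2 (YHR174W) went from 37.0% ± 2.76 (SD, n = 2) labelled in total RNA to 13.2% ± 4.09 in polysomes. Ribosomal protein genes were lower in 126 of 137 (132 adjusted over the list alone; median -1.06), with RPS12 (YOR369C) at 30.1% ± 1.22 and 10.2% ± 1.61. Ergosterol and cell wall genes were lower in 31 of 35 (33 adjusted over the list alone; median -1.30), chaperones in 26 of 27 (median -1.08), histones in 10 of 10 (median -1.23), respiratory genes in 37 of 40 (38 adjusted over the list alone, given second in what follows; median -1.14) and amino acid biosynthesis genes in 45 of 57 (49; median -1.13). Translation factors were lower in 29 of 38 (31 adjusted over the list alone; median -1.05), TCA cycle genes in 14 of 17 (16; median -1.09), general stress genes in 22 of 32 (23; median -1.08) and hexose genes in 11 of 17 (12; median -1.24). Camera, which sets a list against all other genes, passed these 11 lists, with adjusted p = 1.81e-16 for glycolysis and 4.04e-20 for ribosomal proteins. Both were lost at adjusted p = 0.181 with an estimated correlation, as were the other 9 lists, at 0.181 to 0.299. Glucose-repressed genes were lower in 12 of 27 (13 adjusted over the list alone; median -1.03), glycogen genes in 12 of 21 (median -1.05), ribosome biogenesis genes in 16 of 62 (13; median -0.85), mRNA decay genes in 9 of 37 (median -0.94) and cell cycle regulators in 2 of 32 (1; median -1.03), and these lists did not pass. For the last 3 the camera statistic pointed up, against the sign of the median. By edgeR 1850 of 5382 genes were lower in polysomes and 0 higher, with 2622 lower and 1 higher at an unadjusted p under 0.05. Conversions per covered T gave 890 lower, and a reference set to the transcriptome-wide labelled share 1 lower and 17 higher. Without replicate 1 or 2 of total RNA in glucose 903 and 438 were lower, and without replicate 1 or 2 of polysomes in glucose 932 and 593, with 3 higher without the first of these polysome libraries.

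Without glucose few genes differed between polysomes and total RNA in their labelled share: 39 of 5382 were higher and 10 lower by edgeR. On simulated data this test recovered 12.1% of genes changed by 1 (log2) and 42% of those changed by 2. The few calls therefore do not show that labelled copies were not enriched. Since the time of 4TU relative to the withdrawal is not given, labelled copies need not be those made after it. Ribosomal protein genes were higher in 8 of 137 and lower in 1 (26 and 1 adjusted over the list alone; median 0.36), with RPL34A (YER056C-A) at 0.321% ± 0.209 (SD, n = 2) in total RNA and 1.82% ± 0.366 in polysomes. RPL14B (YHL001W) went the other way, from 22.5% ± 6.11 in total RNA to 1.51% ± 0.566 in polysomes, against 0.165% (8 of 4838 reads) in total RNA without glucose and 4TU. Translation factors were higher in 2 of 38 (6 adjusted over the list alone; median 0.27), these being TIF34 (YMR146C), a subunit of initiation factor eIF3, at 1.74 ± 0.351 (log2 ± SE) and EFB1 (YAL003W), an elongation factor subunit, at 1.11 ± 0.257. The phosphatase gene GPP1 (YIL053W, 1.30 ± 0.282) was the called glycolysis gene of 21 (2 adjusted over the list alone), IDH2 (YOR136W, 1.51 ± 0.330) the called TCA gene of 17, and HIS4 (YCL030C) and THR4 (YCR053W) the called amino acid genes of 57. HXT1 (YHR094C), a low-affinity glucose transporter, was the called hexose gene of 17, at -2.53 ± 0.667. The genes of largest change rested on few labelled reads, such as YMR209C with 1 of 303 reads in total RNA and 16 of 72 in polysomes, QRI1 (YDL103C) with 3 of 1151 and 20 of 307, and FKH2 (YNL068C) with 18 of 224 and 0 of 318. The 1253 tested genes of the list higher at 30 min of the chase had a median of -0.18, with 0 higher and 2 lower (0 and 0 adjusted over the list alone; camera p = 0.00137, and p = 0.339 with an estimated correlation). The 994 tested genes of the lower list had a median of 0.35, with 21 higher and 3 lower (41 and 4 adjusted over the list alone; camera p = 0.000116, and p = 0.195 with an estimated correlation).

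Camera passed ribosomal proteins (adjusted p = 6.72e-08), translation factors (0.00310) and ribosome biogenesis (0.0418; median 0.55, 0 of 62 called by edgeR), and each was lost at adjusted p = 0.955 with an estimated correlation. No other list passed, and none of the heat shock, general stress, glycogen, mRNA decay, respiratory, cell cycle, histone and ergosterol members was called by edgeR. Over all genes 477 were higher and 291 lower at an unadjusted p under 0.05. Glucose-repressed genes had 0 of 27 called by edgeR (1 lower adjusted over the list alone; median -0.33; adjusted p = 0.132). Glycolysis genes had a median of -0.10 and TCA genes one of -0.04 although camera pointed up, and chaperones one of 0.03 although it pointed down. For general stress (median -0.15, mean 0.003), mRNA decay (0.13 and -0.006) and ergosterol genes (-0.05 and 0.06) the mean had the other sign. The counts depended on single libraries, with 16 higher and 2 lower without replicate 1 of total RNA without glucose, 73 higher without replicate 1 of polysomes without glucose, and 204 higher and 94 lower without its replicate 2. A fit of the 4 libraries without glucose alone called 16 and 3 of 4256, subtraction of labelled reads expected from the glucose libraries left 1 and 2, and the transcriptome-wide reference gave 74 and 6. Conversions per covered T called 51 and 8, which shared 18 of the 39 higher genes and 1 of the 10 lower ones, so most called genes depended on the measure of label.

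The test of the difference itself asked whether the labelled odds in polysomes over total RNA changed with withdrawal. The contrast itself had a median over all genes of -1.02 with glucose and 0.02 without it, so a higher value here mostly mirrors the depletion in glucose. It need not mean that new copies gained on polysomes after withdrawal. Ribosomal protein genes were higher without glucose in 103 of 137 and lower in 1 (119 and 1 adjusted over the list alone; median log2 change 1.49), with RPS19A (YOL121C) at 3.26 ± 0.462 (SE, n = 2 per group) and RPL34A at 3.34 ± 0.519. Glycolysis genes were higher in 16 of 21 (18 adjusted over the list alone; median 1.51), among them GPP1 (2.40 ± 0.372), and translation factors in 21 of 38 (28 adjusted over the list alone, given second in what follows; median 1.397), among them TIF34 (2.80 ± 0.436). Amino acid biosynthesis genes were higher in 33 of 57 (38 adjusted over the list alone; median 1.46), ergosterol and cell wall genes in 21 of 35 (24; median 1.30), chaperones in 17 of 27 (21; median 1.18), respiratory genes in 19 of 40 (26; median 1.07), TCA genes in 9 of 17 (10; median 1.46), histones in 9 of 10 (10; median 1.28) and general stress genes in 9 of 32 (9; median 0.93). Camera passed these 10 lists, with adjusted p = 3.80e-26 for ribosomal proteins, 2.39e-10 for glycolysis, 6.17e-08 for translation factors and 1.92e-07 for amino acid genes, each lost at adjusted p = 0.215 with an estimated correlation, and none of the 10 held. General stress and respiratory genes passed upwards although their medians lay below the 1.11 of all genes. Hexose genes (5 of 17, 8 adjusted over the list alone; median 1.004), glucose-repressed genes (4 of 27; median 0.999), glycogen genes (6 of 21; median 1.06), ribosome biogenesis genes (12 of 62, 13; median 1.44), mRNA decay genes (5 of 37; median 1.11) and cell cycle regulators (1 of 32; median 1.57) did not pass, the last 2 with a camera statistic pointing down.

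By edgeR 944 of 5382 genes were higher in that difference and 5 lower. The 5 were RPL14B (-2.10 ± 0.424), SUB1 (YMR039C), REC107 (YJR021C), GAL3 (YDR009W) and FKH2. GAL3 had 32 of 3363 reads labelled in total RNA without glucose and 0 of 1276 in polysomes. Set against the transcriptome-wide labelled share, 2 genes were higher and 2 lower, and the median over all genes went from 1.11 to -0.11. Conversions per covered T gave 361 higher and 1 lower, and subtraction of labelled reads expected from the glucose libraries 160 and 1. Without replicate 1 of total RNA in glucose 522 were higher and 1 lower, without its replicate 2 233 and 1, and without replicate 2 of polysomes in glucose 500 and 1. Lower genes numbered 3 and 8 without replicate 1 or 2 of total RNA without glucose, and 11 and 18 without replicate 1 or 2 of polysomes without glucose.

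In total RNA the labelled share was lower after withdrawal in nearly every gene. HXT7 stood at -7.23 ± 0.252 (log2 odds ± SE, n = 2 per group), the chaperonin gene HSP10 (YOR020C) at -7.83 ± 0.262, and RPL3 (YOR063W) at -7.63 ± 0.257 with 57.3% ± 0.523 (SD) labelled in glucose and 0.674% ± 0.0877 after withdrawal. All tested members of 15 of the 16 lists were lower, also adjusted over the list alone, and of ribosome biogenesis 61 of 62. List medians ran from -5.80 for ribosomal proteins and -6.00 for glucose-repressed genes to -7.06 for chaperones, with -6.49 for all genes. Camera weighs genes by their precision and passed 13 lists, among them chaperones (adjusted p = 2.62e-12), respiratory genes (4.72e-13) and ribosomal proteins (1.12e-19), each of these lost at adjusted p = 0.128 with an estimated correlation and none of the 13 kept. Ribosomal protein, general stress, hexose, glycolysis, translation factor and amino acid genes passed downwards although their medians lay above that of all genes. Cell cycle regulators pointed up (adjusted p = 0.0254, and adjusted p = 0.296 with an estimated correlation) against the sign of their median of -6.46. Ribosome biogenesis genes (median -6.67), mRNA decay genes (-6.67) and glucose-repressed genes did not pass. By edgeR 5361 of 5382 genes were lower and 0 higher, the same numbers as at an unadjusted p under 0.05. The largest fitted changes were in VAB2 (YEL005C), MSB2 (YGR014W), QDR1 (YIL120W), AFT1 (YGL071W) and SPO7 (YAL009W), which had 0 labelled reads after withdrawal, so their fitted sizes are not given. Relative to the transcriptome-wide labelled share 183 genes were higher and 692 lower.

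During the chase the labelled share fell more slowly without glucose in most genes. The share of GAS1 (YMR307W), a cell wall glucan transferase, went from 67.2% ± 0.944 (SD, n = 2) at 0 min to 23.4% ± 1.37 at 30 min with glucose, and from 67.7% ± 0.240 to 69.0% ± 1.45 without it. For NOP58 (YOR310C), a nucleolar protein of ribosome assembly, it went from 49.3% ± 1.18 to 18.8% ± 0.680 with glucose and from 51.3% ± 1.02 to 54.5% ± 2.78 without. All 62 ribosome biogenesis genes had a higher slope without glucose (median 0.75 log2 odds per 10 min), as did all 38 translation factors (0.62), all 137 ribosomal protein genes (0.45), all 57 amino acid genes (0.51) and 33 of 34 ergosterol and cell wall genes (0.54), against a median of 0.39 over all genes. General stress genes were higher in 24 of 32 (21 adjusted over the list alone; median 0.28) and glucose-repressed genes in 18 of 25 (median 0.28), less than genes at large. Camera passed ribosome biogenesis (adjusted p = 1.39e-41), translation factors (2.13e-25) and ergosterol and cell wall genes (9.16e-17), and these held at adjusted p = 0.0154 with an estimated correlation. Ribosomal proteins (6.92e-34) were lost at adjusted p = 0.140 with an estimated correlation, amino acid genes (3.38e-12) at 0.115, and downwards against other genes, opposite to the sign of their medians, general stress (0.000450) at 0.148 and glucose-repressed genes (0.000168) at 0.115.

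Of the other lists, respiratory genes (39 of 40 higher; median 0.35; camera adjusted p = 0.00994, and adjusted p = 0.623 with an estimated correlation) and glycolysis genes (20 of 21; 0.37; adjusted p = 0.0165, and adjusted p = 0.591 with an estimated correlation) passed upwards, although both medians lay below the 0.39 of all genes. Glycogen genes (16 of 21; 0.27; adjusted p = 0.00828, and adjusted p = 0.377 with an estimated correlation) passed downwards against other genes. Chaperones (25 of 27; 0.36), hexose genes (16 of 17; 0.33), mRNA decay genes (36 of 37; 0.40), TCA genes (16 of 17; 0.34), cell cycle regulators (31 of 32; 0.53) and histones (10 of 10; 0.34) did not pass as lists. Counts adjusted over the list alone were the same except where given. By edgeR 4867 of 5224 genes had a higher slope without glucose and 2 a lower one, RGI1 (-0.17 ± 0.0685 per 10 min; SE from 28 libraries taken as independent) and FIT3 (YOR383C, -0.13 ± 0.0542). With limma on 1 slope per course of the log2 labelled share 5043 genes were higher and 0 lower, so both lower calls were lost. That setting changes the measure as well as the replicate unit, and which of them moved the counts was not tested. Both turned positive over 0 to 20 min (0.101 and 0.0237), for labelled reads over library totals (1.69 and 0.42) and for labelled reads per spike-in read (1.498 and 0.20). The largest differences were in GCD2 (YGR083C, 1.36 ± 0.264), URA7 (YBL039C, 0.97 ± 0.0541), UTP15 (YMR093W), NAN1 (YPL126W) and SGD1 (YLR336C), of which URA7, UTP15 and SGD1 turned to -0.24, -0.21 and -0.00628 for labelled reads per spike-in read. The median gene lost 1 log2 unit of labelled odds in 13.03 min with glucose and in 26.1 min without. Relative to the transcriptome-wide share 2116 genes were higher and 45 lower, and lower genes numbered 4 and 0 without course 1 or 2 with glucose, and 1 without either course lacking glucose.

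**Figure D3:**
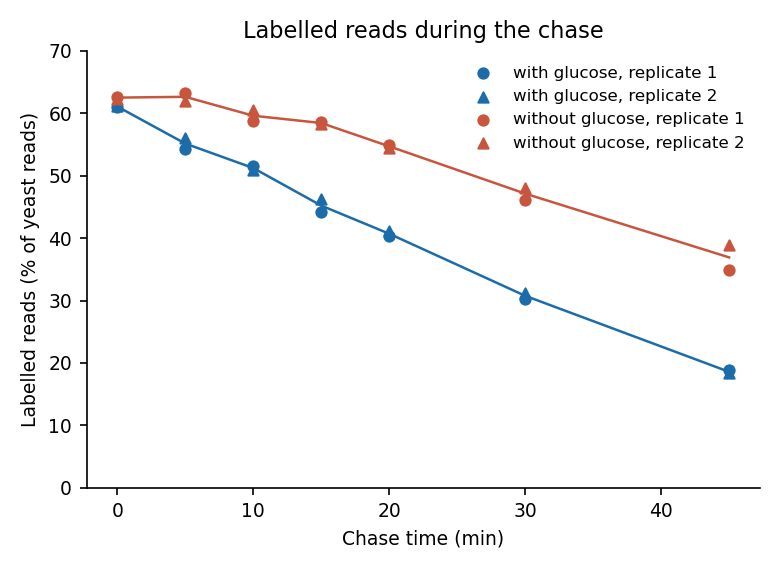
Labelled reads as a percentage of yeast reads (y axis) against chase time in minutes (x axis) for each library (points, by replicate) with the mean of 2 replicates (lines). The share fell from 61.1% to 18.6% over 45 min with glucose and from 62.5% to 36.9% without.

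The labelled share depends on the loss of labelled copies and on the making of unlabelled and of further labelled ones, so labelled reads were also counted per read of the added spike-in RNA, which leaves the net of loss and of new labelled copies. On that scale labelled reads of ribosomal protein genes had median slopes of -0.744 and -0.653 log2 per 10 min in the courses without glucose and -0.0875 and -0.292 with it. Ribosome biogenesis genes had -0.876 and -0.824 without glucose and -0.540 and -0.772 with it. The slope difference of RPL3 turned from 0.56 to -0.26, that of GAS1 from 0.84 to -0.0762, that of NOP58 from 0.755 to -0.28 and that of the elongation factor gene TEF4 (YKL081W) from 0.689 to -0.24. Labelled reads of general stress genes came to 4.02 and 5.63 times the 0 min value at 30 min in the 2 courses without glucose, against 0.495 and 0.418 times with it. Those of glucose-repressed genes came to 4.21 and 5.47 times without glucose. Over all genes they came to 0.413 and 0.530 times without glucose and 0.660 and 0.412 times with it. By edgeR on labelled reads per spike-in read, 2313 of 5224 genes had a higher slope without glucose and 444 a lower one. The protocols of the labels do not describe how the spike-in was added.

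**Figure D4:**
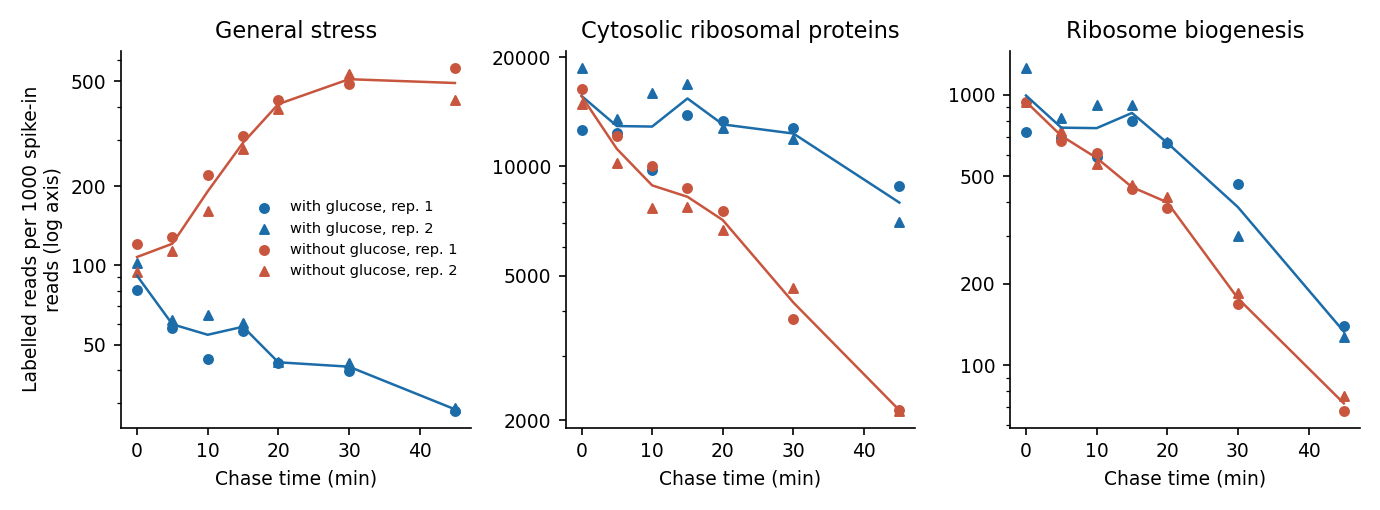
Labelled reads of 3 gene lists relative to the spike-in reads (y axis, log axis) against chase time in minutes (x axis) for each library (points, by replicate) with the mean of 2 replicates (lines). In the courses without glucose, general stress genes lay at 4.02 and 5.63 times their 0 min value at 30 min and ribosomal protein genes at 0.232 and 0.311 times.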

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

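All tests of explanations in this part were chosen after the results were seen, 2 of them replaced earlier ones whose values are also given, and those on general stress, ribosomal protein and biogenesis mRNA in the chase were added or split after their slopes were seen.

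The following results differ between groups by a test of the difference itself. Polysome association changed with glucose withdrawal in 449 genes upwards and 442 downwards by edgeR. The labelled odds in polysomes over total RNA differed between the conditions in 944 genes upwards and 5 downwards. The median of these odds was -1.02 with glucose and 0.02 without it, so the upward calls mostly mirror the depletion in glucose. The slope of the labelled share in the chase differed in 4867 genes upwards and 2 downwards. The change in abundance at 30 min of the chase differed from that in total RNA of the 4TU libraries in 1334 genes upwards and 1069 downwards of 5534, and with library totals in 2844 and 380, where the median of all genes moved to 0.80.

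Without glucose, ribosomal protein mRNAs were lower in the chase and not in total RNA of the 4TU libraries, with a median difference of -2.28 (log2). Part of the chase value was a rise with glucose relative to all genes. There reads of the list per spike-in read came at 30 min to 1.74 and 1.08 times the 0 min value. All genes came to 1.33 and 0.806 times. How much of the difference between the experiments this explains was not tested. Scaling as the whole cause is argued against by a median of -1.57 with library totals and -2.32 with the DESeq2 size factors. A single deviating library is argued against by medians from -2.15 to -2.51 when each of the 8 libraries was left out, and an earlier test on genes with at most 1% multimapped reads was void, since it kept 136 of 137 genes (median -2.29). The strain remains open: in the unreplicated total RNA of the chase strain without 4TU the list stood at -0.95, between the values of both experiments. The sets also differ in labelling and chase, which was not tested.

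After withdrawal the median gene of total RNA had 1.36% labelled reads, while single genes differed widely, such as VAB2 with 0 labelled reads, RPL34A with 0.321% and RPL14B with 22.5%, and 262 genes lay over 5%. Uptake throughout the withdrawal at the rate in glucose is argued against for most genes at least 8-fold higher at 30 min of the chase. Of these 257 genes, 225 and 223 had at least 200 reads and were not among the 262 genes over 5%. Their medians were 1.62% and 1.48%, against medians of 55.4% and 61.2% in glucose under the same filter. The medians alone could not decide this, since the filter holds them low, so the argument rests on the number of genes kept. An earlier test of their share over that of little-changed genes gave 1.18 and 1.16. Labelled reads carried over from the glucose libraries accounted for 9.89% of the labelled reads at most by a fitted rate. Strain variants read as conversions are argued against by shares of at least 1.27% without the genes above 5%. Labelling as in glucose before the withdrawal, with loss of the labelled share as in the chase, is argued against. The share of total RNA was 1.72% ± 0.0974 (SD, n = 2) after withdrawal and 50.1% ± 1.03 in glucose. In the chase without glucose, which used another strain, it went from 62.5% at 0 min to 47.1% at 30 min. What produced these labelled reads otherwise stays open. The titles say post-labeling (4TU), and no source says whether 4TU came before or after the withdrawal.

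The labelled share fell more slowly without glucose. Fewer new unlabelled copies as the whole cause stays open, since the median slopes of labelled reads per spike-in read were -0.427 and -0.406 without glucose and -0.503 and -0.652 with it, all apart in 1 direction but by 0.0762 between the nearest courses, against 0.149 between the courses with glucose. In the general stress genes, labelled reads per spike-in read had median slopes of 0.632 and 0.707 (log2 per 10 min) without glucose. With glucose the slopes were -0.340 and -0.451. Without glucose these labelled reads came at 30 min to 4.02 and 5.63 times the 0 min value. Over library totals they came to 7.17 and 8.20 times. Loss of labelled copies and new unlabelled ones cannot raise a labelled count. The values therefore argue against a chase without new labelled copies in these genes. How much of the slope difference such copies explain was not tested. For ribosomal protein mRNA the slopes of labelled reads per spike-in read lay lower without glucose by a gap of -0.36 (spread between courses 0.205). This argues against a slower net loss of labelled copies there. Unlabelled reads of that list had median slopes of -0.552 and -0.530 without glucose and 0.477 and 0.296 with it. For ribosome biogenesis mRNA the gap was -0.0521 (0.232), and unlabelled reads had slopes of -0.826 and -0.839 without glucose and 0.208 and -0.0214 with it. Slower decay itself stays open for both lists, since slopes of labelled reads are the net of loss and of new labelled copies. The 4 courses make 3 splits, too few for a share under 0.05, and the real one, 1 of the 3, gave 4869 genes and the highest other gave 0. Every other split sets a course of each condition on both sides, so a difference between conditions lowers its count. The splits therefore do not settle chance.

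Citrine, a reporter that no comparison used and that was singled out after its values were seen, had 263 to 3349 reads in the 4TU libraries. It was counted as 0 in the chase libraries and those without 4TU, where a feature missing from a library also counts as 0. It was labelled in 46.7% (exact 95% interval 43.9 to 49.5) and 55.1% (53.4 to 56.8) of reads of total RNA in glucose, and in 2.37% (1.33 to 3.88) and 0.845% (0.341 to 1.73) after withdrawal. In polysomes it was labelled in 37.0% and 31.1% in glucose, and in 2.28% (0.842 to 4.90) and 0.698% (0.144 to 2.03) after withdrawal. Spike-in reads, which no comparison of labelling used, were labelled in 0.346% to 0.496% of reads of the chase libraries.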

How the results depend on the processing

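Alternatives were planned before the data were examined, except those said here to be added after seeing the data. The cause of a change was not tested unless given. Of 3969 values for named genes under alternatives, 3551 kept direction and side of the threshold, 350 lost the threshold, 24 gained it and 44 turned. For the labelled share without glucose the simulated test recovered 42% of genes changed by 2 (log2), and whether depth or the spread between replicates limits it was not tested.

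Leaving out all genes with multimapped reads tested fewer genes: 336 higher and 332 lower of 1252 in total RNA, 15 and 18 of 89 in the chase, and 28 and 21 of 1252 for polysome association. It gave 0 and 0 of 1131 for the labelled share without glucose, 4 lower with glucose, 7 higher and 0 lower for their difference, 1123 lower in total RNA, and 13 and 0 of 21 for the slope. Library totals gave 1052 higher in total RNA, 224 for polysome association, and 2844 and 380 for the chase against total RNA (added). Spike-in scaling (added) gave 1186 higher in the chase. The transcriptome-wide reference gave 74 and 6 without glucose, 17 and 1 with glucose, 2 and 2 for the difference, 183 and 692 in total RNA, and 2116 and 45 for the slope. By construction it removes a shift common to all genes. Conversions per covered T gave 890 lower with glucose and 361 and 1 for the difference. Subtracting labelled reads expected from the glucose libraries (added) left 1 and 2 without glucose and 160 and 1 for the difference. The libraries without glucose alone (added) gave 16 and 3 of 4256 genes, from 4 libraries. Omitting genes over 5% labelled (added) left 3 lower for the difference. A minimum of 10 reads gave 1 higher with glucose. For the slope, 0 to 20 min gave 12 lower, limma 0 lower, labelled reads over library totals 175 lower, and per spike-in read (added) 2313 and 444.

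Leaving out each library gave 1308 to 1510 higher and 1120 to 1403 lower in total RNA, 1883 to 1977 and 1720 to 1837 in the chase, 178 to 494 and 174 to 487 for polysome association. It gave 16 to 204 and 2 to 94 for the labelled share without glucose, 0 to 3 and 438 to 932 with glucose, 233 to 1084 and 1 to 18 for their difference. It gave 5309 to 5352 lower in total RNA, 4387 to 4744 and 0 to 4 for the slope, and 963 to 1419 and 788 to 1281 for the chase against total RNA. The lone library left in a group is assumed to vary like the other groups. The libraries behind the moves over 1.5 times are, for polysome association, replicate 1 (178 and 174) and 2 (212 and 205) of total RNA without glucose. For the labelled share without glucose they are replicate 1 of total RNA (16 and 2) and polysomes without glucose 1 (73 higher) and 2 (204 and 94). With glucose they are total RNA 1 (903 lower) and 2 (438) and polysomes 1 (932, and 3 higher) and 2 (593). For the difference they are total RNA 1 (522 and 1) and 2 (233 and 1) and polysomes 2 (500 and 1) in glucose, and total RNA 1 (3 lower) and 2 (8) and polysomes 1 (11) and 2 (18) without it. For the slope they are courses 1 (4 lower) and 2 (0) with glucose and 1 (1) and 2 (1) without.

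An estimated correlation left 1 of 12 list calls in total RNA, 6 of 12 in the chase, 0 of 7 for polysome association, 0 of 3 for the labelled share without glucose, 0 of 11 with glucose, 0 of 10 for the difference, 0 of 13 in total RNA labelling and 3 of 10 for the slope, and ended the calls of the induced genes at medians of 0.37 and -0.18. The library-wide ratio in glucose was 0.428 from conversions and 0.700 for the median gene.

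Deviations of same-numbered libraries had a median correlation of 0.056 between chase times of a condition (-0.399 to 0.512) and of -0.0439 among the 4TU groups (-0.0702 to 0.361), so the numbers were not taken as pairs. The highest were 0.440 to 0.512 among 10, 15 and 20 min without glucose, so pairing is not excluded there. With the replicate number as a block, 1626 and 1608 were called in total RNA, 2116 and 1917 in the chase, 467 and 453 for polysome association. It gave 58 and 17 for the labelled share without glucose, 1 and 1535 with glucose, 894 and 6 for the difference. It gave 5357 lower in total RNA labelling, 4879 and 2 for the slope and 1427 and 1141 for the chase against total RNA.

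The values that turned direction were these (log2). Conversions gave -0.93 for YGR117C without glucose and -0.00722 for POP2 in the difference. The transcriptome-wide reference gave, with glucose, HOR7 0.0521, ALD4 0.0102, GAR1 0.36, SDH4 0.0278, CIT2 0.0728, RNR1 0.32 and HTB1 0.0465. It gave HXT2 -0.0376 and HXT7 -0.0562 in the difference and PUB1 0.16 in total RNA. Subtraction gave -2.79 for TEF4 in the difference. For the slope, 0 to 20 min gave RGI1 0.101, FIT3 0.0237 and PNC1 -0.0776. Labelled reads over library totals gave URA7 -0.0282, UTP15 -0.00285, RGI1 1.69, FIT3 0.42, RPL3 -0.0339, NOP58 -0.0596, RPA190 -0.0454, TEF4 -0.0183, YEF3 -0.12 and RNR1 -0.15. Labelled reads per spike-in read gave URA7 -0.24, UTP15 -0.21, SGD1 -0.00628, RGI1 1.498, FIT3 0.20, GPP1 -0.01005, RPS12 -0.10, RPL3 -0.26, NOP58 -0.28, RPA190 -0.26, TEF4 -0.24, YEF3 -0.34, LSM1 -0.00685, MET6 -0.11, RNR1 -0.37, CLN2 -0.14, GAS1 -0.0762 and ERG3 -0.0867.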

Other observations

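The test in this part of the chase against total RNA was chosen after the data were seen. Between the experiments, glycogen and trehalose genes rose more in the chase at 30 min than in total RNA of the 4TU libraries, with a median difference of 1.62 (log2) and 18 of 21 members higher by edgeR. General stress genes were higher in 18 of 32 and lower in 3 (median difference 1.51), and respiratory genes higher in 21 of 40 with none lower (median difference 0.68), while translation factors were lower in 27 of 38 and higher in 1 (median difference -0.81). Camera passed these lists with adjusted p = 2.40e-09, 4.47e-06, 0.00263 and 0.000109 in that order, and with an estimated correlation they were lost, at adjusted p = 0.538, 0.591, 0.860 and 0.591. Glucose-repressed genes were higher in 5 of 29 and lower in 8 (median difference -0.20) and did not pass (camera adjusted p = 0.633). These values rest on TMM factors. With library totals the median of all genes was 0.80, that of translation factors -0.10 (6 higher and 5 lower) and that of glucose-repressed genes 0.52 (12 higher and 1 lower), while respiratory genes were higher in 36 (median 1.39).

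In the unreplicated libraries of the chase strain without 4TU, the change of polysomes over total RNA after withdrawal had a median of 1.197 for hexose genes and 1.06 for chaperones, both above all of 10000 random lists matched on expression, and 0.36 for amino acid biosynthesis genes, at percentile 99.6. Ribosomal protein genes stood at -0.90, below all random lists. These values compare single libraries, not conditions.

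Labelled odds of the median gene halved in 13.03 min with glucose and 26.1 min without, and labelled reads per spike-in read in 17.04 and 24.1 min. For ribosomal protein genes labelled reads per spike-in read halved in 51.9 min with glucose and 14.2 min without by the fit of both courses, although the slopes of the courses with glucose were -0.0875 and -0.292 (log2 per 10 min), so the first value depends on the course. For ribosome biogenesis genes the values were 15.2 and 11.8 min. These are the net of loss and of new labelled copies and not times of decay. Without glucose, 585 of 5224 genes had a positive fitted slope of labelled reads per spike-in read, and with glucose 2, which was not tested gene by gene. Yeast reads per spike-in read went from 91.0 and 80.2 at 0 min to 46.4 and 37.6 at 45 min in the courses without glucose, and from 72.1 to 91.8 and from 105.7 to 77.9 in those with it. Genes at least 8-fold higher at 30 min had 6.24 and 9.41 times as many labelled reads per spike-in read at 30 min as at 0 min without glucose, and 0.298 and 0.261 times with it.

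Labelled reads carried 1.32 to 1.75 conversions each in the chase libraries and 0.335 to 0.614 in the 4TU libraries. A labelled read holds at least 1 conversion if both are counted alike, so the counts of the 4TU libraries followed different rules, which the sources used here do not give. This bears on their labelled shares and on the values from conversions per covered T. Reads of the 10 most abundant genes made up 7.62% to 11.4% of chase libraries and 13.8% to 29.1% of the 4TU libraries.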
